A study of Mus musculus with 16 samples.

How the data were processed

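RNA was measured in sorted mouse bone marrow progenitors at 40 weeks of age. Multipotent progenitors (MPP) were lineage-negative, Kit-positive, Sca1-positive, CD48-positive and CD150-negative, and granulocyte-monocyte progenitors (GMP) were lineage-negative, Kit-positive, Sca1-negative, CD150-negative and CD16/32-positive, per the labels' protocols. Each population was taken from 4 mice labelled WT, whose genotype field gives a floxed Tet2 allele, and 4 mice labelled Tet2KO, so that the 16 libraries fall into 4 groups of 4. The mouse numbers in the labels show that 3 mice per genotype gave both populations. Libraries were made from 2 ng of amplified total RNA and sequenced as single-end reads of 75 bp, per the labels' protocols.

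Reads were aligned with STAR to mm10 and genes were compared with DESeq2, per the submitters' processing notes, which give no versions. The read counter and the gene annotation are not given in the sources used here. The authors' deposited tables, one per population, hold the comparison of Tet2KO with WT for 23420 gene symbols each, and no values per library. The mean column is a normalized signal per gene over all libraries of that population, as deposited by the authors. The fold change column is the log2 fold change of Tet2KO over WT with its standard error (SE), per the file headers, and its direction rests on the name the authors gave to each deposited table. The p-value and the adjusted p-value per gene are the authors' own, as deposited. Recomputation showed that the p-value is the two-sided normal p of the log2 fold change over its SE, within a relative difference of 0.00172 on the log scale, and that the adjusted value is the Benjamini-Hochberg value over the genes with the status OK, within 2.4e-05. A gene has that status when its mean is at least 10 and it was not marked as an outlier. Genes marked as outliers carry no p-value. The SE reached at most 0.388 in MPP and 0.359 in GMP and was small again at the lowest means. Fold changes shrunken towards 0 give such a pattern, so the changes of weakly expressed genes may be understated.

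The depth of each library is unknown, since no total per library is in the tables. The means summed to 9436210 in MPP and 11033900 in GMP. The ribosomal RNA gene Rn45s took 6.71% of that sum in MPP and 9.06% in GMP. Precision followed the mean. For genes with a mean of 10 to 50 the median SE of the log2 fold change was 0.350 in MPP and 0.303 in GMP, and for genes above 1000 it was 0.102 in MPP and 0.0744 in GMP. Each table holds 27 gene names that a spreadsheet had turned into dates, of which 1 was called in GMP. These rows stay in the counts of called genes and out of every step that uses names.

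Genes were called at the authors' adjusted p of 0.05. The 29 gene lists fixed before the data were examined were tested with limma 3.58.1 (cameraPR, R 4.3.3) on the log2 fold change over its SE, with a preset inter-gene correlation of 0.01, where at least 5 members had been tested, and Benjamini-Hochberg adjustment over the lists. A correlation estimated from the libraries could not be had from tables without values per library. The difference between populations was tested as the difference of both log2 fold changes over the root of their summed squared SEs, two-sided, over the 17660 genes with a p-value in both tables, with Benjamini-Hochberg adjustment. This treats the errors of both tables as independent, although mice are shared. Overlap and direction were tested with Fisher's exact test, two-sided. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest. Gene positions come from the GENCODE annotation of the mm10 assembly, which 99.0% of the tested symbols in each table matched directly or through a synonym.

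The genes named below follow a rule fixed before the data were examined. For each population, Tet2 comes first. The 10 higher and 10 lower called genes with the largest log2 fold change and a mean of at least 50 follow, with the 5 per direction of smallest adjusted p. Up to 4 called members of each list were taken, or where none was called up to 2 of smallest p as values, and for the difference between populations up to 5 genes per direction with a mean of at least 50 in both tables. Symbols that are only clone or model numbers were counted but not named. Genes named outside the rule are said to be so. Some genes that the rule takes are not reported here.

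The calls, the set test and the test of the difference were tested on simulated data, and the overlap, direction, correlation and outlier counts were not. Simulated statistics had unit noise drawn independently for each gene, whereas the robust spread of the real ones was 1.16 in MPP and 1.35 in GMP. The simulated effects were not shrunken, and genes of a list were not correlated. The shares below therefore hold for these simpler settings and may overstate what the real data allow. With the SEs of the MPP table, 81.8% of genes changed by 1 on the log2 scale and 37.6% of those changed by 0.5 were called, out of 11841 genes. With the SEs of the GMP table these shares were 92.2% and 64.3%, out of 11487 genes. A list of 28 genes whose statistic was shifted was recovered in a share of 200 draws that rose with the shift. A shift of 0.5 was recovered in 9% of draws in MPP and 1% in GMP, a shift of 0.75 in 40.5% and 17.5%, a shift of 1 in 84% and 69%, and a shift of 1.5 in 100% of draws in both. A first version of this simulation used a single draw per table at a shift of 0.75 and did not recover the list, and it was replaced by the repeated draws. The test of the difference, run on 11050 simulated pairs of values, fewer than the 17660 genes of the real adjustment, called 77% of genes that differed by 1. Alternatives to the threshold, the filter, the set test, the error model and the null distribution were tried, and the closing section gives their main effects. Leaving out libraries, regrouping them and refitting the counts were not run, because the tables hold no values per library.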

Results

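The comparisons ask which transcripts differ between blood progenitors labelled Tet2KO and WT. TET2 is an enzyme that oxidizes 5-methylcytosine in DNA. MPP are early progenitors that can still give rise to several blood lineages, and GMP are later progenitors committed to granulocytes and monocytes. Each comparison sets 4 libraries labelled Tet2KO against 4 labelled WT within a population. All fold changes, SEs and adjusted p-values of single genes are those of the authors' deposited tables, made with DESeq2.

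Tet2 itself (chromosome 3, 133463679 to 133545139, minus strand, mm10) was higher in the libraries labelled Tet2KO. In the authors' deposited table its log2 fold change was 0.44 (SE 0.0992, adjusted p = 0.00551) in MPP and 0.35 (SE 0.0748, adjusted p = 0.000409) in GMP. The value is given for the gene as a whole and not per exon, so it does not show whether a deleted part is missing and does not check the labels. Since it goes against a simple loss of transcript, each direction below is that of the libraries labelled Tet2KO and rests on the authors' naming of the tables.

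In MPP, 73 of 11859 tested genes were called in the authors' deposited table, 41 higher and 32 lower in Tet2KO. With an empirical null the number was 17, and with an absolute log2 fold change of at least 1 it was 12 higher and 14 lower. Among called genes with a mean of at least 50, Mmp2, a matrix metalloproteinase, rose by 1.31 on the log2 scale (SE 0.258, adjusted p = 0.000363) and Sdc2, a cell-surface heparan sulfate proteoglycan, by 1.30 (SE 0.246, adjusted p = 0.000188), in the authors' deposited table. The transcription factor genes Sox6 (1.02), Hmga2 (0.98) and Zbtb16 (0.97) also rose, as did Scube3 (1.14), the cyclic nucleotide phosphodiesterase Pde2a (1.08), Trim30b (0.99), Lpcat2 (0.92) and Inpp4b (0.91), all log2 fold changes from the authors' deposited table. The lowest values among called genes with such a mean were those of Emp1 (-1.36), Mrvi1 (-1.35), Chdh (-1.31), Nucb2 (-1.23), the chemokine receptor Ccr9 (-1.22), Cnn3 (-1.18), Jakmip1 (-1.03) and Synpo2 (-1.03) in the authors' deposited table. Chdh, choline dehydrogenase, had the smallest adjusted p of the table (5.65e-09, SE 0.181). Gfi1, a transcriptional repressor needed for granulocyte and lymphoid development, fell by 1.00 (SE 0.233, adjusted p = 0.00743), and P2ry14, Ncf1 and Skp1a fell by 0.78, 0.60 and 0.48 in the authors' deposited table.

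**Figure D1:**
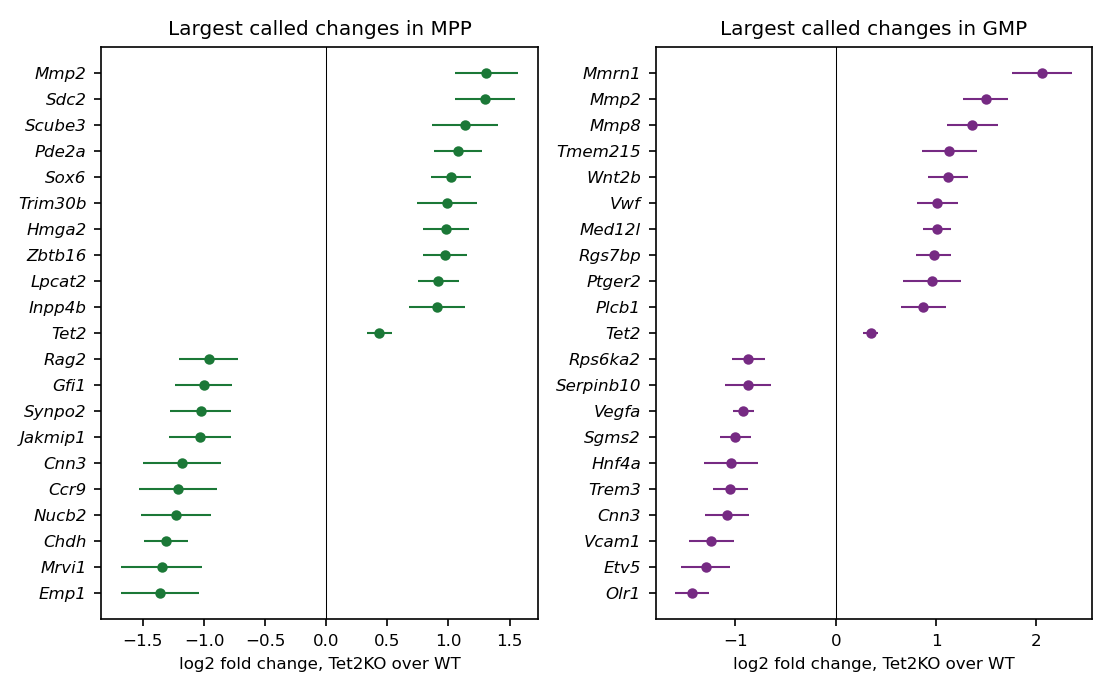
Log2 fold change of Tet2KO over WT (x axis) for the called genes with the largest change and a mean of at least 50, and for Tet2, in MPP (left) and GMP (right). Points are the values and bars the SEs of the authors' deposited tables, and Tet2 lies above 0 in both panels, at 0.44 and 0.35.

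B cell lineage genes were lower in MPP. All 6 tested B cell lineage genes had negative values (cameraPR, adjusted p = 0.00142), with 1 called over all genes and 3 adjusted over the list alone. A further 3 members were marked as outliers and not tested, 2 of them above 0. The called member was Rag2, part of the recombinase that rearranges antigen receptor genes, which fell by 0.96 (SE 0.241, adjusted p = 0.0169) in the authors' deposited table. With a minimum mean of 50 too few members were left for a test. Of the T and NK cell genes none was called, and Lck had a value of -0.86 and Klrk1 of 1.15 in the authors' deposited table.

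Megakaryocyte genes were higher in MPP as a list of 15 tested members (cameraPR, adjusted p = 0.00263), with 1 called over all genes, and 5 higher and 2 lower adjusted over the list alone. Interferon response genes were higher (30 tested, adjusted p = 0.00168), although none of them was called, over all genes or adjusted over the list alone. Gbp2 and Oas2 had values of 0.40 and 0.54 in the authors' deposited table. With log2 fold changes in place of the statistic the adjusted p was 0.0676 for the megakaryocyte list and 0.083 for the interferon list. At a preset correlation of 0.05 cameraPR gave an adjusted p of 0.0324 for the megakaryocyte list and 0.0359 for the interferon list.

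Cytosolic ribosomal protein genes were lower in MPP, with 71 of 73 tested members below 0, a median log2 fold change of -0.19 and an adjusted p of 2.16e-14 (cameraPR). Rps14 was the member called over all genes, with a fall of 0.65 (SE 0.128, adjusted p = 0.000363) in the authors' deposited table, and 3 were called adjusted over the list alone. Replication-dependent histone genes were lower as well, with 33 of 34 tested members below 0, a median of -0.48 and an adjusted p of 2.86e-11, and no member was called. A further 14 of 48 histone genes with a mean of at least 10 were marked as outliers and not tested, 29.2% against 3.50% of all such genes. All 14 lay below 0, but this adds no support. Without values per library, whether a single library carries the fall of the histone list was not tested. G2 and M phase genes were lower (24 of 28 members below 0, adjusted p = 0.00173) with no member called, and with log2 fold changes in place of the statistic the adjusted p was 0.0877. These lists hold co-regulated genes, and a correlation between genes could not be estimated from the tables. The adjusted p depends on the preset correlation. At 0.05 in place of 0.01, cameraPR gave 1.06e-05 for the ribosomal list, 1.06e-05 for the histone list and 0.0359 for the G2 and M phase list.

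Among other lists without a call as a whole, single members were called in MPP in the authors' deposited table. Runx1, a transcription factor of definitive blood formation and a gene of the myeloid malignancy list, rose by 0.47 (SE 0.106, adjusted p = 0.00551). Tfec, of the E-box factor list, rose by 0.56, Tie1, an endothelial receptor of the stromal and endothelial list, by 0.77, and the p53 target Sesn1 fell by 0.45 in the authors' deposited table.

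In GMP, 456 of 11503 tested genes were called in the authors' deposited table, 201 higher and 255 lower in Tet2KO. The balance of directions depended on the setting. With an empirical null 36 were higher and 36 lower, after recentring on the median 229 were higher and 224 lower, and 31 were higher and 14 lower with an absolute log2 fold change of at least 1. The largest rise was that of Mmrn1, a platelet and endothelial secreted protein, at 2.06 on the log2 scale (SE 0.302, adjusted p = 1.57e-08) in the authors' deposited table. Mmp2 (1.496), the neutrophil collagenase Mmp8 (1.36), Tmem215 (1.13), Wnt2b (1.12), the platelet adhesion protein gene Vwf (1.01), Med12l (1.01), Rgs7bp (0.98), the prostaglandin receptor gene Ptger2 (0.96) and Plcb1 (0.87) also rose in the authors' deposited table. The largest falls among called genes with a mean of at least 50 were those of Olr1 (-1.43), the transcription factor gene Etv5 (-1.30), the adhesion molecule gene Vcam1 (-1.24), Cnn3 (-1.09), Trem3 (-1.05), Hnf4a (-1.05), Sgms2 (-0.9996), the growth factor gene Vegfa (-0.92), Serpinb10 (-0.87) and Rps6ka2 (-0.87) in the authors' deposited table. Vegfa (SE 0.108, adjusted p = 2.11e-13), Olr1 and Gnai3 had the smallest adjusted p-values.

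As lists, monocyte genes were higher and primary granule genes lower in GMP, with members on both sides of 0 in each. The monocyte and macrophage list was higher (11 of 17 tested members above 0 and 6 below, cameraPR adjusted p = 0.00426). Of its members 4 were called over all genes and 5 adjusted over the list alone. Its called members were Ms4a6c (0.56), the macrophage colony-stimulating factor receptor gene Csf1r (0.56), the lysosomal protease gene Ctss (0.67) and Cd68 (0.34) in the authors' deposited table. Irf8, a transcription factor of monocyte and dendritic cell fate, rose by 0.50 (SE 0.131, adjusted p = 0.00936) in the authors' deposited table, although it is not in the monocyte list, and its own lists, those of dendritic cell genes and lineage transcription factors, did not pass (adjusted p = 0.0624 and 0.771). Primary granule genes were lower (9 of 13 tested members below 0 and 4 above, cameraPR adjusted p = 0.00336). Of these, 3 were called over all genes and 6 adjusted over the list alone. Ctsg, Ms4a3 and Srgn fell by 0.31, 0.40 and 0.31 in the authors' deposited table. Cytokine receptors were higher as a list (23 tested, adjusted p = 0.00426), with rises of Il6st (0.62), Il6ra (0.38) and Csf1r and a fall of Ifngr1 (-0.45) in the authors' deposited table. With the rank-based set test the adjusted p was 0.239 for the monocyte list, 0.0588 for the granule list and 0.0588 for the receptor list, and with log2 fold changes in place of the statistic it was 0.129 for the receptor list. The late neutrophil list did not pass (3 of 9 tested members above 0, adjusted p = 0.890), and of its called members Mmp8 rose while Pglyrp1 fell by 0.77 (SE 0.180, adjusted p = 0.00178) in the authors' deposited table.

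Mast cell and basophil genes were lower in GMP, with all 8 tested members below 0 (cameraPR, adjusted p = 7.42e-06), 4 called over all genes and 5 adjusted over the list alone. The called members were the mast cell protease gene Cma1 (-1.71), Csrp3 (-0.94), the transcription factor gene Gata2 (-0.37) and Lmo4 (-0.35) in the authors' deposited table, of which Cma1 and Csrp3 had means under 50. Megakaryocyte genes were higher (11 tested, adjusted p = 0.0248), through Pf4 (1.35), Vwf (1.01) and F2r (0.69) in the authors' deposited table. For that list the adjusted p was 0.0673 with a preset correlation of 0.05, 0.0566 with a minimum mean of 50 and 0.259 with the rank-based set test, but 0.00251 with log2 fold changes in place of the statistic, 0.00497 without genes of several lists and 0.000425 with outlier-marked members included, an alternative added after the values were seen.

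Cell cycle genes were lower in GMP. Of the G2 and M phase genes 27 of 28 lay below 0 (cameraPR, adjusted p = 5.01e-08), with 5 called over all genes and 8 adjusted over the list alone, among them Ect2 (-0.36), Ccnb1 (-0.33), Cdk1 (-0.39) and Plk1 (-0.28) in the authors' deposited table. Of the S phase genes 25 of 29 lay below 0 (adjusted p = 0.00114) with no member called. Histone genes (40 of 46 below 0, adjusted p = 2.02e-08) and ribosomal protein genes (56 of 75 below 0, adjusted p = 7.45e-05) were lower too, with 5 and 4 members called over all genes and 11 and 4 adjusted over the list alone. Hist1h2be fell by 0.52 and Rpl19 by 0.22 in the authors' deposited table. Interferon response genes were higher (29 tested, adjusted p = 0.00123), with calls for Irf9 (0.45) and Ly6e (0.16) in the authors' deposited table.

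Called stem cell and Hox genes lay on both sides of 0 in GMP, and neither list passed (adjusted p = 0.0663 and 0.362). Mecom (-0.85), Angpt1 (-0.30), Hoxa9 (-0.60) and Hoxa10 (-1.03) fell in the authors' deposited table. Of the methylation enzymes Tet3, a paralogue of Tet2, rose by 0.23 (SE 0.0624, adjusted p = 0.0131) in the authors' deposited table, and that list did not pass (adjusted p = 0.771). The E-box factor list did not pass either (adjusted p = 0.291), although Max (0.33) and Mycn (1.10) rose and Mxi1 (-0.34) fell in the authors' deposited table. The adjusted p of the lists that did not pass ran from 0.148 to 0.997 in MPP and from 0.0518 to 0.890 in GMP.

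**Figure D2:**
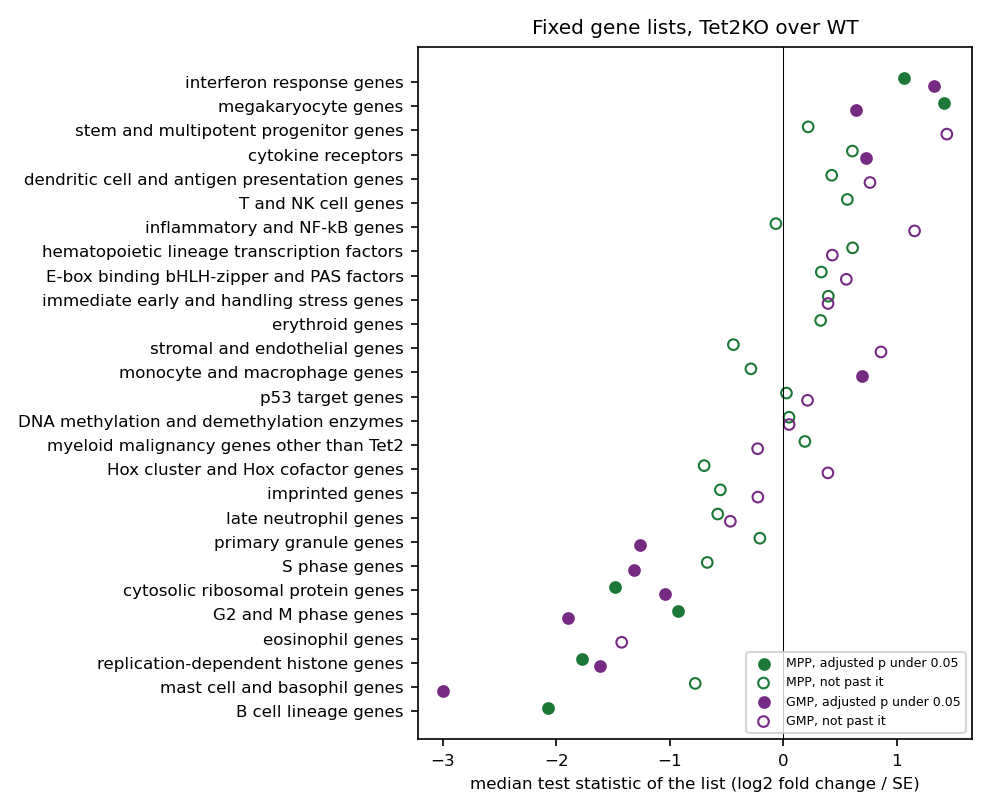
Median test statistic (log2 fold change over SE, x axis) of each fixed gene list with at least 5 tested members (rows), in MPP (green) and GMP (purple). Filled points passed an adjusted p of 0.05 in the set test, which 6 of 26 lists did in MPP and 10 of 24 in GMP.

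The genes called in MPP and in GMP overlapped. Of 11050 genes tested in both, 8 were called higher in both tables, where independent lists would share 0.529 (Fisher's exact test, p = 3.65e-08), and 7 were called lower in both, where 0.555 would be shared (p = 8.63e-07). None was called in opposite directions. Those higher in both were Mmp2, Zbtb16, Pdgfrb, Pde4a, Gdap10, Dpp4, Svil and Tet2, and those lower in both were Chdh, Cnn3, Etv5, Gfi1, P2ry14, Ncf1 and Skp1a. Across 9102 genes with a mean of at least 50 in both tables, the log2 fold changes of both populations had a Pearson r of 0.397 and a Spearman rho of 0.373, which describe genes and not replicates. Pdgfrb, Pde4a, Gdap10, Dpp4 and Svil are named outside the rule, because they belong to this overlap. The tables are not independent, since 3 of 4 mice per genotype gave both populations, and the expected numbers do not allow for that.

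**Figure D3:**
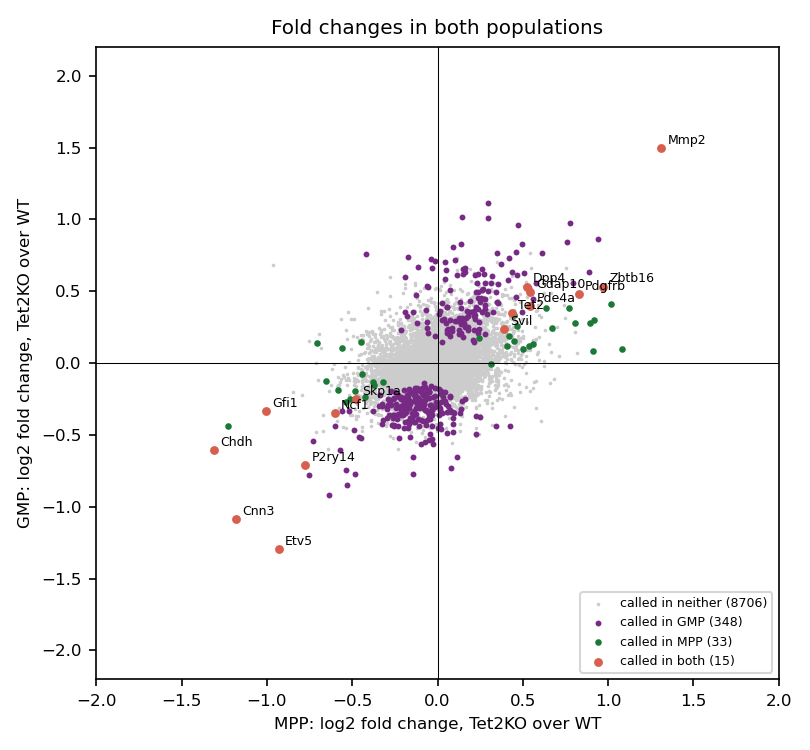
Log2 fold change of Tet2KO over WT in MPP (x axis) against GMP (y axis) for the 9102 genes with a mean of at least 50 in both of the authors' deposited tables. The 15 labelled genes were called in both populations and lie in the upper right or lower left quadrant.

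The share of called genes that were higher was 56.2% in MPP and 44.1% in GMP, a difference that did not pass Fisher's exact test (p = 0.0585). After recentring on the median the shares were 58.1% and 50.6% (Fisher's exact test, p = 0.259), so the majority in GMP turned to higher. The effect itself differed between populations for 8 genes. Pde2a (1.08 in MPP and 0.10 in GMP, adjusted p of the difference = 0.0441) and Gstm1 (0.08 and -0.73, adjusted p = 0.0206) were lower in GMP relative to MPP. Max (-0.18 and 0.33), Tpm4 (-0.19 and 0.60), Sesn1 (-0.45 and 0.15) and Rbm47 (-0.97 and 0.68) were higher in GMP relative to MPP, each with an adjusted p of 0.0206, from the values of the authors' deposited tables. Pf4 and Mrvi1 also passed, with a mean under 50 in at least 1 table. With independent errors none passed at an adjusted p of 0.01. When the errors were taken as correlated at 0.346, 49 genes passed. That value is the correlation of both statistics across genes, which mixes shared effects with shared errors. It is therefore not an estimate of the error that shared mice bring. SEs were smaller in GMP, but the share of called genes was also higher there at similar SEs. Of GMP genes with a mean of 100 to 1000 (median SE 0.118) 3.90% were called. Of MPP genes above 1000 (median SE 0.102) 0.707% were called. Smaller SEs alone therefore do not account for the larger number of calls in GMP, which is not itself a test of a larger effect.

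Genes marked as outliers, which carry no p-value, were frequent in several of the fixed lists, at 13 of 18 erythroid genes in MPP and 14 of 18 in GMP with a mean of at least 10, so these lists rest on part of their members. For primary granule genes 8 of 15 were marked in MPP, for monocyte and macrophage genes 9 of 22 in MPP and 4 of 21 in GMP, for B cell lineage genes 3 of 9 in MPP, for cytokine receptors 8 of 29 in MPP, for megakaryocyte genes 6 of 17 in GMP, and for mast cell and basophil genes 5 of 13 in GMP.

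**Figure D4:**
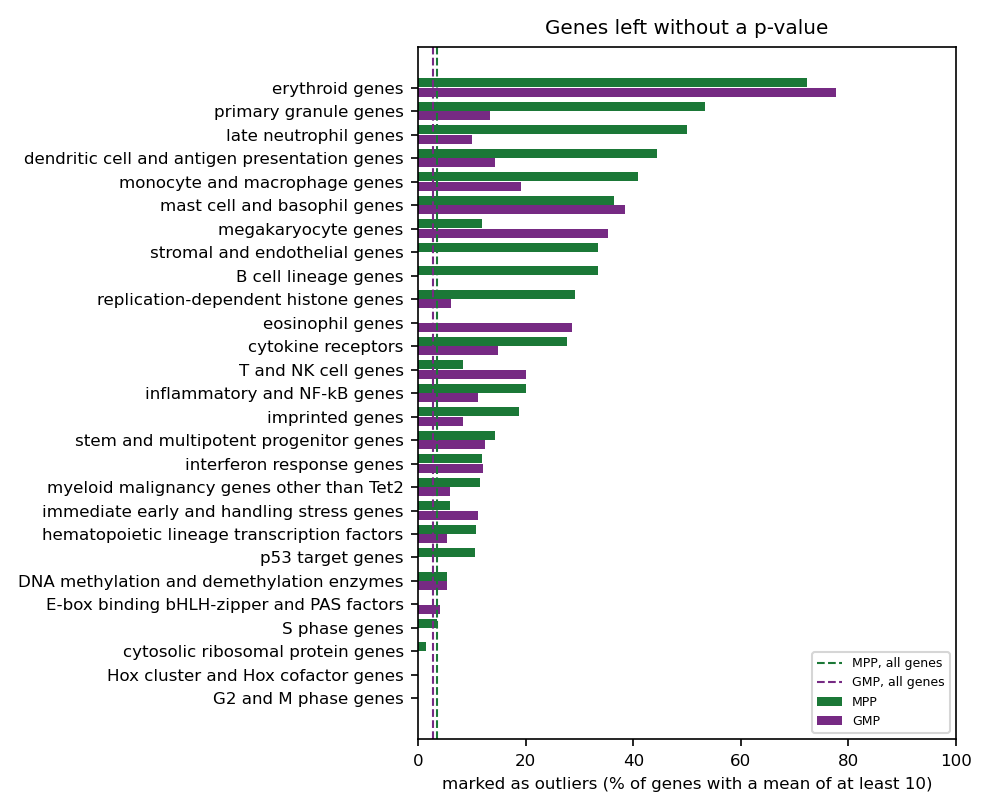
Share of each fixed list's genes with a mean of at least 10 that the authors' deposited table marks as outliers (x axis, percent), in MPP (green) and GMP (purple). Dashed lines give the share over all genes, 3.50% in MPP and 2.65% in GMP.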

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

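The tests of the marked erythroid genes, of the mice shared by both populations, of length and GC, and of lists on the difference between populations were all chosen after the results they address were seen.

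For 8 genes the change differed between the populations by a test of the difference itself. The difference of log2 fold changes, GMP minus MPP, was -0.81 for Gstm1, 0.50 for Max, 2.29 for Mrvi1, 1.65 for Rbm47, 0.78 for Tpm4, 0.59 for Sesn1, 2.27 for Pf4 and -0.98 for Pde2a, from the authors' deposited tables. Of 21 lists with at least 5 members tested in both tables, 4 passed the set test on that difference. The median statistic of the difference was 0.636 for 73 ribosomal protein genes and 0.663 for 33 histone genes (cameraPR, adjusted p = 5.54e-05 and 0.00370). Both lists were lower in both populations, and the positive sign means a smaller fall in GMP. It was -1.66 for only 6 primary granule genes and 0.582 for 12 inflammatory and NF-kB genes (adjusted p = 0.00416 and 0.0328). The inflammatory list passed in neither population alone. These tests also treat the errors of both tables as independent, although mice are shared.

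Genes marked as outliers have no p-value and enter no comparison, yet 9 of the 430 marked in MPP and 20 of the 314 marked in GMP would pass with the normal p of their log2 fold change over SE. Among these, named after their values were seen, are Dntt, Ms4a2 and Ccnd1. The template-independent DNA polymerase gene Dntt had a log2 fold change of -1.32 in MPP in the authors' deposited table. The IgE receptor gene Ms4a2 had -1.28 in GMP, and the cyclin gene Ccnd1 -1.11 in MPP and -0.92 in GMP, in the authors' deposited table. The tables hold no values per library, so whether a single library carries these changes was not tested. The marked genes are therefore not counted as called. With marked genes included, an alternative added after the values were seen, 86 genes passed in MPP and 484 in GMP.

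Marked genes were frequent in some lists of blood lineages, but also among histone genes in MPP (14 of 48), and not in every lineage list, with 1 of 12 for T and NK cells in MPP. Of erythroid genes with a mean of at least 10, 13 of 18 were marked in MPP and 14 of 18 in GMP, against 3.50% and 2.65% of all such genes. Random lists matched on the mean held 0.69 and 0.44 marked genes on average, and all 10000 held fewer than observed, which argues against expression level as the cause. In GMP 13 of the 14 marked erythroid genes lay below 0 (exact binomial test of signs, two-sided, p = 0.00183), as erythroid cells in a single WT library would give, but so would any change shared by these co-regulated genes, and the test treats genes as independent. In MPP they split into 7 above and 6 below 0 (same exact test, p = 1), each within 1 SE of 0, and a single library cannot be told apart from several there; the gate excluded Ter119-positive cells, and no values per library exist to decide.

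Ribosomal protein and histone genes were lower in both populations. Short transcripts and GC content were weighed as a cause by removing the trend of the statistic on both over all tested genes. The lists stayed lower in the set test after that. In MPP cameraPR gave p-values of 8.00e-10 for ribosomal protein genes and 3.94e-08 for histone genes, and in GMP of 0.00225 and 4.44e-09, so the trend is not the whole cause. The labels give a minimum RNA integrity number of 8. RNA integrity, amplification and cell cycle state per library stay open, since no values per library are given for them.

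The fold changes of MPP and GMP were correlated, and the same trend does not account for that, since the Pearson r of the test statistics was 0.414 before its removal and 0.397 after. The 3 mice per genotype that gave both populations cannot be told apart from a shared effect of the genotype, because the tables hold no values per mouse.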

How the results depend on the processing

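No paired analysis was possible because the deposited tables hold no values per library, although mice are shared between populations. For the same reason leaving out each library, other splits of the libraries, an estimated inter-gene correlation and a refit with another count tool were not run, so how often chance splits of the libraries give as many calls is not known.

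The number of called genes depended on the threshold and the null. At an adjusted p of 0.01 it was 36 in MPP and 198 in GMP, at 0.1 it was 768 in GMP, and with an absolute log2 fold change of at least 1 it was 26 (12 higher, 14 lower) and 45 (31 higher, 14 lower). With no filter on the mean it was 65 and 349, which ended 1 of 30 named calls in MPP and 12 of 76 in GMP, and with a minimum mean of 50 it was 61 and 444. With an empirical null, which divides the statistics by their robust spread of 1.16 in MPP and 1.35 in GMP, it was 17 and 72, by construction fewer. Of the named called genes, 12 of 30 in MPP and 30 of 76 in GMP stayed called under that null. The genes whose effect differed numbered 0 at 0.01, 49 with correlated errors and 17 with an empirical null. With a minimum mean of 50 in both tables they numbered 6, without Pf4 and Mrvi1, and still 6 when the shrinkage was also undone, an alternative added after the values were seen. Genes called in the same direction in both populations numbered 27 at 0.1 and 8 at 0.01, and at 0.1 a further 1 was called in opposite directions. With log2 fold changes in place of the statistic 3 lists passed in MPP and 13 in GMP, where cytokine receptors were lost (adjusted p = 0.129) and the dendritic cell, eosinophil, inflammatory and stem cell lists gained. With ranks 6 passed in each population; the cause was not tested. The majority direction of the calls turned with the minimum fold in both populations and with recentring in GMP (229 higher, 224 lower), while no called list changed its direction. The SEs have the pattern of shrunken fold changes, so changes of weakly expressed genes may be understated, and the depth of each library is unknown.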

Other observations

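The tests here were all chosen after the result was seen.

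Some genes lower in GMP lie near Tet2 on chromosome 3. That chromosome as a whole did not pass a test for an excess of calls in GMP (26 of 533 tested genes, Fisher's exact test, adjusted p = 0.728 over 20 chromosomes), and chromosome 1 alone passed (41 of 647, 21 higher and 20 lower, adjusted p = 0.0499). A candidate explanation is DNA of another strain carried along with the targeted allele, which could change neighbouring genes without any effect of TET2. Within 30 Mb of Tet2, 13 genes, 7.14% of those tested, were called in GMP, 12 of them lower, against 3.90% elsewhere (Fisher's exact test, p = 0.0339). The distance was picked after the pattern was noticed. Of 8 tests, at 5, 10, 20 and 30 Mb in both populations, this was the only 1 with an unadjusted p under 0.05, and none passed adjustment over the 8 (adjusted p = 0.271 for 30 Mb in GMP and 0.421 in MPP). The labels give both genotypes a targeted Tet2 allele. If both carry the same allele, DNA flanking it would be shared and would not differ between them, which weighs against this explanation. Strain variants were not tested, so the explanation is neither shown nor excluded. The called genes nearest to Tet2 in GMP were Ppa2 (-0.39, 0.160 Mb away), Sgms2 (-0.9996, 2.10 Mb) and Ostc (-0.41, 2.80 Mb) in the authors' deposited table. Of these, Ppa2 and Ostc are named outside the rule. Other genes named above also lie within 30 Mb. In GMP these are Lmo4 (10.7 Mb), Cnn3 (12.1 Mb), Vcam1 (17.4 Mb), Gnai3 (25.4 Mb), Gstm1 (25.5 Mb) and Wnt2b (28.6 Mb), of which Wnt2b alone was higher. In MPP they are Synpo2 (10.3 Mb) and Cnn3, both lower.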
